A study of Homo sapiens with 60 samples.

How the data were processed

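The series holds RNA-seq of the human monocytic line MonoMac 6 in 5 genotypes, WT, 2 knockout clones (KO1, KO2) and 2 knock-in clones (KI1, KI2), each without treatment, with LPS (1 µg/ml, 6 h), after differentiation (72 h with 1 ng/ml TGF-beta and 50 nM calcitriol), and after differentiation with LPS. Each of the 20 groups has 3 libraries, 60 in all. WT is 1 line and each KO or KI is 1 single clone, so the libraries are replicates within a line or clone. The treatment protocol in the labels reads as if every culture was differentiated, which the sample titles contradict. The titles were followed, and CYP24A1 levels were checked against them.

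Per the submitters' processing notes, reads were aligned to GRCh38 with STAR 2.6.0c and counted per gene with RSEM 1.3.0. The deposited values have the unit the headers call signal: expected counts per gene, divided by 1 factor per library that the authors set separately within each of 16 tables of 6 libraries. Each table pairs KO1 with WT, KO2 with WT, KI1 with KO1 or KI2 with KO2 in 1 condition. The labels name neither the scaling method nor the annotation. The factor was found from the values, since each library is 1 constant times numbers with at most 2 decimals, and 36 libraries that occur in 2 tables were identical after division (relative tolerance 1e-06). All 96 columns were used. In 1 table the 3 untreated WT columns are all headed replicate 1, and in another the KO1 headers lack the word for differentiation. Both were settled from identical libraries in a second table. Of nonzero values per library, 75.1 to 77.6% in KI and 86.9 to 89.4% in WT and KO lay within 0.01 of a whole number. Whole read counts were thus not recovered, and count models were not used. The plan, written before the data were examined, had allowed for whole counts.

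Identifiers numbered 58395, of which 57754 were matched to a symbol and 58275 to a position in GENCODE 29. Where gene models overlap, reads can lie on 1 model in some libraries and on the other in the rest. This held for 7SK, 7SL1 and RMRP, which are given as sums of both models or not at all, except that 1 model of 7SL1 is printed where its sign changed. SIGLEC14 lies within the model of SIGLEC5 on the same strand, and SIGLEC14 values carry the same limit. Readthrough genes, histones and ribosomal protein genes with near-identical copies are subject to it too.

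Depth was 5.64 to 15.4 M expected reads in WT, 3.78 to 14.7 in KO1, 5.78 to 7.94 in KO2, 13.2 to 17.6 in KI1 and 11.2 to 20.5 in KI2. Genes with a mean of at least 10 in a table were tested. In data simulated from these libraries, changes of 1.5, 2 and 4-fold in KO1 against WT were recovered for 42.4, 65.7 and 92.4% of genes. Of 144 calls over 12764 genes 11 were false. For KI1 against KO1 the shares were 9.38, 40.3 and 83.9%, and 2 of 87 calls over 13513 genes were false. For the change of the KO effect with LPS after differentiation they were 9.38, 55.4 and 71.9%. There 3 of 91 calls over 13186 genes were false. The precision reflects the spread between libraries and, for genes near the limit of 10, counting error.

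Each comparison was made within 1 table with limma 3.58.1 in R 4.3.3, by limma's trended moderated test on log2 of the value plus 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Both-clone counts are genes past the threshold in both tables. For differences between clones, KO1 and KO2 libraries were put on 1 scale through the WT libraries that their tables share, and were contrasted directly. The WT level cancels in that contrast. The WT libraries stayed in the fit, so their spread entered the variance behind the SE. Differences between conditions were tested as differences of within-condition changes, averaged over both clones, so that levels were never tested across conditions. Folds are 2 to the power of the log2 change with the pseudocount of 1. Reads per M (per 1e+06 expected reads of the library) are given only as levels. Correlations of libraries of 1 number between the groups of a table were all over 0.1 in 0 of 16 tables. No pairing was therefore used, and the labels do not say whether numbers pair. Across conditions, libraries of 1 number deviated together in the KI clones. All 3 correlations passed 0.1 in 5 of 6 pairs of groups there (-0.02 to 0.71). In WT and KO this held in 1 of 9 (-0.0030 to 0.22). KI1 and KI2 libraries of 1 number also deviated together without treatment (0.23, 0.21 and 0.35). In the other conditions replicates 2 and 3 did (0.22 to 0.44) and replicate 1 did not (-0.09 to 0.07). Counts and averages over both KI clones are thus not from fully independent series.

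Gene lists for myeloid, metabolic and stress pathways were written before the data were examined. A list was tested where at least 5 members were, with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. Counts of members past the threshold are given over all genes and adjusted over the list alone.

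Genes were named by a rule fixed before the data were examined. It takes ALOX5, the 5 genes up and 5 down with the largest mean change in both clones (mean of at least 50, replicates not overlapping), up to 2 members per list and condition with the smallest adjusted p in both clones, or 1 member passing in 1 clone, the 5 largest KO changes among genes opposite in KI, and 3 genes per test of a difference. The rule gave 298 genes, and 5 more were chosen after their values were seen. Some genes that the rule gives are not reported here.

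The alternatives were a pseudocount of 5, no filter on low values, upper-quartile rescaling, a spread taken from all libraries of the condition, a replicate block, each library left out in turn, and an estimated correlation for lists. Precision weights by voom and a fit of protein-coding genes alone with upper-quartile scaling, and a replicate block across conditions, were added after the data were seen. Other splits of the libraries were counted, all 10 for 3 against 3 and 100 seeded draws otherwise. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Reads were not used here, so editing of ALOX5, isoforms and the strand of single reads were not examined.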

Results

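5-lipoxygenase, the product of ALOX5, makes leukotrienes from arachidonic acid in myeloid cells, and the series asks which transcripts depend on it in the human monocytic line MonoMac 6. RNA was compared between WT cells, 2 knockout clones (KO1 and KO2) and 2 knock-in clones (KI1 and KI2). Each genotype was untreated, given LPS, differentiated with TGF-beta and calcitriol, or differentiated and then given LPS, with 3 libraries in each of the 20 groups. The labels do not say whether the 3 libraries of a group came from separate cultures, so each p-value below measures only the spread between these libraries. Values are normalized expected counts with their standard deviation unless another unit is given.

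ALOX5 RNA was present in both KO clones, and its level moved in different directions between clones and conditions. In untreated KO1 cells ALOX5, at 45374176 to 45446119 of chromosome 10, stood at 22.8 ± 5.59 against 56.4 ± 15.2 in WT (log2 change -1.27, SE 0.33, adjusted p = 0.0209). In untreated KO2 cells it stood at 73.3 ± 16.98 against 51.8 ± 14.1 (log2 change 0.50, adjusted p = 0.264). With LPS it was lower than WT in KO1 (log2 change -1.42, adjusted p = 0.00375) and higher in KO2 (1.81, adjusted p = 8.82e-06). After differentiation alone the change was -0.49 in KO1 (adjusted p = 0.34) and -1.07 in KO2 (adjusted p = 0.01). With LPS as well it was 0.08 and 0.47 (adjusted p = 0.766 and 0.205). KI2 held less ALOX5 RNA than KO2 without treatment (log2 change -1.52, adjusted p = 0.0018) and with LPS (-1.85, adjusted p = 1.65e-05). KI1 differed from KO1 by 0.18 (adjusted p = 0.735) and 0.91 (adjusted p = 0.0712). After differentiation KI1 was below KO1 by -0.86 (adjusted p = 0.0233) and, with LPS as well, by -0.84 (adjusted p = 0.00471). KI2 then differed from KO2 by 0.24 (adjusted p = 0.572) and -0.67 (adjusted p = 0.0679). Counts summed over a gene do not show whether a short edit lies in the transcript, so they do not check either genotype. The call in untreated KO1 was lost without KO1 replicate 1 (-1.26), KO1 replicate 3 (-1.10) or WT replicate 1 (-1.06), and that in differentiated KO2 without KO2 replicate 2 (-0.87). The call in differentiated KI1 was lost without KO1 replicate 1 (-0.79), KO1 replicate 3 (-0.68), KI1 replicate 1 (-0.64) or KI1 replicate 2 (-0.77), and all 3 of these calls were lost with the spread taken from all libraries of the condition. Other ALOX5 values passed the threshold when 1 library was left out. These were KI1 with LPS without KI1 replicate 1 (1.19), differentiated KI2 without KI2 replicate 2 (0.67), KO2 with both treatments without KO2 replicate 2 (0.80), and KI2 with both without KO2 replicate 2 (-0.99) or KI2 replicate 1 (-0.91).

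CYP24A1 encodes the 24-hydroxylase that breaks down calcitriol, and it separated the differentiated cultures from the others. It lay between 23.7 and 462 reads per M in the 30 differentiated libraries and at or under 0.572 in the 30 others. These are levels relative to the total of each library, and they were not tested. After differentiation CYP24A1 differed from WT by a log2 change of 1.43 in KO1 (SE 0.54, adjusted p = 0.155, but past the threshold without WT replicate 3, at 2.20) and -0.26 in KO2 (adjusted p = 0.774). CYP24A1, and below CAMP, CD14, MYC and IFIT1, were chosen after their values were seen.

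**Figure D1:**
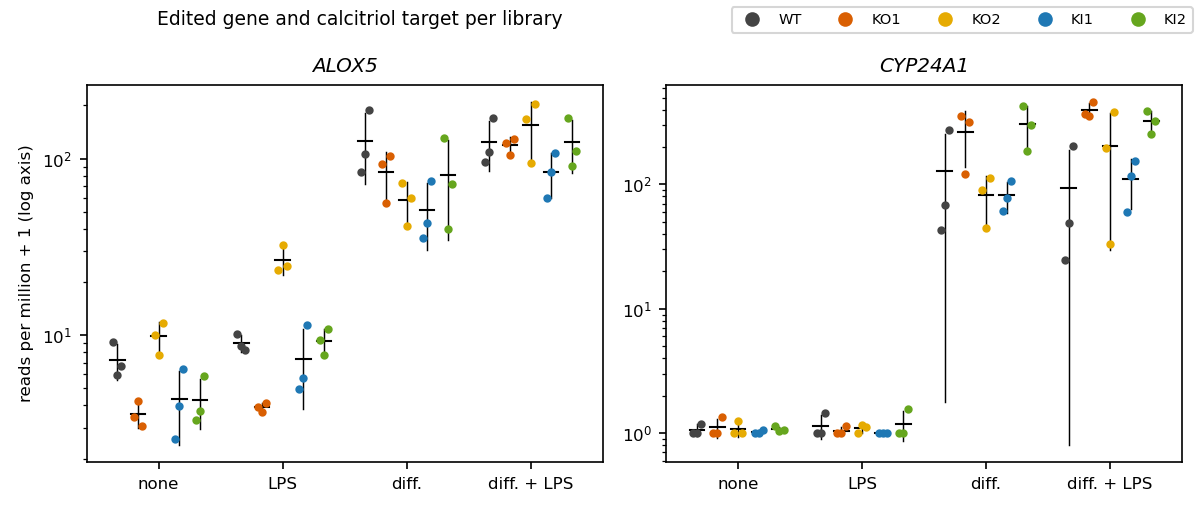
ALOX5 and CYP24A1 in reads per M plus 1 on a log axis, 1 point per library, for WT, KO1, KO2, KI1 and KI2 in each condition, with a horizontal bar at the mean and a vertical line for the SD. CYP24A1 is at or above 23.7 reads per M in every differentiated library and at or under 0.572 in the rest.

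Without treatment TANC1, a scaffold protein first described at synapses, was the transcript with the largest mean rise in both KO clones among those the selection rule named. It stood at 283 ± 71.5 in KO1 against 4.32 ± 1.81 in WT (54.2-fold, log2 change 5.76, SE 0.33, adjusted p = 3.14e-07) and at 122 ± 31.7 in KO2 against 3.97 ± 1.65 (25.0-fold, log2 change 4.64, SE 0.40, adjusted p = 6.36e-06). The gene lies at 158968671 to 159232659 of chromosome 2. MAGEA1, a cancer-testis antigen normally silent outside the germline (chromosome X, 153179285 to 153183880), was 19.3-fold and 14.4-fold higher in KO1 and KO2, and MYO6, an actin motor of endocytosis, was 5.51-fold and 15.2-fold higher. GRAMD1B, which carries cholesterol from the plasma membrane to the endoplasmic reticulum (chromosome 11, 123358428 to 123627774), fell to 5.64 ± 4.93 from 294 ± 30.7 in KO1 and to 6.03 ± 4.73 from 270 ± 28.97 in KO2, 65.9-fold and 44.0-fold lower (adjusted p = 0.000101 and 1.32e-06). The insulin-receptor adaptor GRB10 was 18.7-fold and 5.67-fold lower, the SRC-family kinase FYN 10.2-fold and 3.91-fold lower, and HLA-DRA, a chain of the MHC class II receptor, 13.3-fold and 2.89-fold lower. The monocyte chemoattractant CCL2 was 4.32-fold higher in KO1 (424 ± 143 against 100 ± 44.7) and 17.7-fold higher in KO2 (1576 ± 431 against 92.0 ± 40.8), while the cytokine TNF was 4.16-fold and 4.02-fold lower.

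By limma with Benjamini-Hochberg adjustment, 1729 of 13015 genes changed in untreated KO1 (765 higher, 964 lower) and 2044 of 12983 in untreated KO2 (992 higher, 1052 lower), of which 559 and 880 changed at least 2-fold. The same direction held in both clones for 575 genes (211 higher, 364 lower), against 132 expected if the calls were independent, and 49 genes went opposite ways. Cytosolic ribosomal protein genes, a family whose near-identical copies share reads, were higher in KO1 for 18 of 47 members and lower for 0 (24 and 0 adjusted over the list alone). Camera gave an adjusted p of 1.57e-09, and 0.305 with an estimated correlation. At its preset correlation camera made 142 calls over all tables, and other splits of the same libraries gave a median of 106. Those splits keep part of the real contrast, so this median does not measure chance. In KO2 0 of the 47 were higher and 5 lower (0 and 3 adjusted over the list alone). Targets of ATF4 and the unfolded protein response were lower in KO1 for 12 of 32 and higher for 0 (16 and 1 adjusted over the list alone, 0.328 with an estimated correlation). The count in KO1 was 1064 without KO1 replicate 1, 1063 without KO1 replicate 2, 925 without WT replicate 1 and 1009 without WT replicate 2. The count in KO2 was 1055 without WT replicate 1, 930 without WT replicate 2 and 1267 without KO2 replicate 1, and the shared count was 249 without WT replicate 1 and 241 without WT replicate 2.

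With LPS TNIP3, an LPS-induced inhibitor of NF-kB signalling (chromosome 4, 121131408 to 121227466), was 10.6-fold above WT in KO1 (log2 change 3.41, SE 0.49, adjusted p = 0.000513) and 35.2-fold above it in KO2 (5.14, SE 0.45, adjusted p = 8.88e-07). P2RY6, a receptor for extracellular UDP that drives phagocytosis, was 7.96-fold and 18.8-fold higher, and CCL2 (chromosome 17, 34255218 to 34257203) was 3.62-fold and 14.6-fold higher. GRAMD1B stayed 41.1-fold and 33.0-fold lower, and GRB10 was 19.0-fold and 46.0-fold lower. KYNU, which cleaves kynurenine in tryptophan breakdown (chromosome 2, 142877498 to 143055832), was listed at 0 in KO1 against 38.5 ± 7.42 in WT. It stood at 3.44 ± 3.42 in KO2 against 35.2 ± 6.77 (log2 change -3.45, SE 0.70, adjusted p = 0.00137). The clones parted on the cytokine IL1B, at 18063 ± 1955 in KO2 against 2410 ± 284 in WT (7.498-fold, log2 change 2.91, SE 0.12, adjusted p = 7e-10) and with a log2 change of 0.28 in KO1 (SE 0.12, adjusted p = 0.156, but past the threshold without KO1 replicate 2, at 0.40). THBS1, the matrix protein thrombospondin 1 that activates TGF-beta (chromosome 15, 39581079 to 39599466), was 44.8-fold higher in KO2 (4964 ± 1111 against 109 ± 16.1). In KO1 it stood at 66.5 ± 13.9 against 119 ± 17.8 (log2 change -0.84, adjusted p = 0.0189), a call lost without KO1 replicate 3 (-0.70), WT replicate 1 (-0.85) or WT replicate 2 (-0.72) and with the spread taken from all libraries of the condition. The interferon-induced IFIT1 was 5.64-fold higher in KO1 and had a log2 change of -0.29 in KO2 (SE 0.56, adjusted p = 0.718), and the growth regulator MYC was 1.71-fold lower in KO2 with -0.13 in KO1 (adjusted p = 0.437).

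LPS gave 1829 changed genes of 12658 in KO1 (856 higher, 973 lower) and 4977 of 12761 in KO2 (2508 higher, 2469 lower), 570 and 1862 of them at least 2-fold. Both clones moved the same way at 854 genes (370 higher, 484 lower; 349 expected) and opposite ways at 207. Interferon-response genes were higher in KO1 for 19 of 35 and lower for 0 (27 and 0 adjusted over the list alone). Their camera adjusted p was 7.88e-14, and 0.376 with an estimated correlation. In KO2 12 of 33 were higher and 2 lower (12 and 2 adjusted over the list alone, 0.599 with an estimated correlation). MYC targets and ribosome biogenesis genes were higher in KO1 for 8 of 36 and lower for 1 (11 and 1 adjusted over the list alone, 0.418 with an estimated correlation). They were lower in KO2 for 28 of 36 and higher for 1 (31 and 1 adjusted over the list alone, 0.295 with an estimated correlation). NF-kB targets were higher in KO2 for 16 of 29 and lower for 1 (16 and 1 adjusted over the list alone, 0.481 with an estimated correlation). In KO1 4 were higher and 4 lower (6 and 5 adjusted over the list alone). Vitamin D receptor targets were higher in KO2 for 15 of 23 and lower for 2 (17 and 2 adjusted over the list alone, 0.0952 with an estimated correlation). The KO1 count was 1105 without KO1 replicate 3, 1000 without WT replicate 1 and 913 without WT replicate 2, and the shared count was 507 without WT replicate 1 and 453 without WT replicate 2.

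After differentiation TANC1 remained 28.1-fold above WT in KO1 (log2 change 4.81, SE 0.34, adjusted p = 1.58e-05) and 19.0-fold above it in KO2 (4.25, adjusted p = 7.14e-06). NDFIP1, an adaptor for NEDD4-family ubiquitin ligases, was 6.51-fold and 8.01-fold higher, and CAMKV, a kinase-like protein of vesicles, was 8.53-fold and 9.31-fold higher. GRAMD1B was 30.8-fold and 47.2-fold lower, and SIGLEC14, an activating sialic-acid receptor of monocytes (chromosome 19, 51642553 to 51646801), was 20.4-fold and 4.78-fold lower. Its model lies within that of SIGLEC5, so reads of the 2 genes can be divided between them. The LPS co-receptor CD14 was 3.27-fold higher in KO1 (4553 ± 259 against 1430 ± 413, adjusted p = 0.000465). Its log2 change in KO2 was -0.14 (adjusted p = 0.756), and the clones differed by 1.84 (SE 0.23, adjusted p = 0.00017). The antimicrobial peptide gene CAMP, a calcitriol target, rose 2.27-fold in KO1 and had a log2 change of -0.64 in KO2 (SE 0.25, adjusted p = 0.106), a difference between clones of 1.82 (SE 0.24, adjusted p = 0.000274). The lysosomal protease CTSD was 2.84-fold lower in KO2 (adjusted p = 1.1e-05), with a log2 change of 0.15 in KO1 (adjusted p = 0.66). KYNU was listed at 0 in both clones, against 9.76 ± 1.49 and 8.58 ± 1.3 in WT, and was under the expression limit for testing.

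Differentiation gave 597 changed genes of 13364 in KO1 (360 higher, 237 lower) and 1650 of 13159 in KO2 (785 higher, 865 lower), 340 and 591 of them at least 2-fold. In both clones 237 changed alike (137 higher, 100 lower; 35.03 expected) and 20 went opposite ways. Vitamin D receptor targets were higher in KO1 for 10 of 29 and lower for 1 (15 and 1 adjusted over the list alone). Their camera adjusted p was 9.16e-08, and 0.478 with an estimated correlation. In KO2 8 of 30 were higher and 2 lower (8 and 3 adjusted over the list alone). Unfolded protein response and ATF4 targets were higher in KO2 for 16 of 32 and lower for 0 (18 and 0 adjusted over the list alone, 0.0918 with an estimated correlation). Phagocyte oxidase and lysosome genes were lower there for 14 of 32 and higher for 0 (17 and 0 adjusted over the list alone, 0.166 with an estimated correlation). The KO1 count was 202 without KO1 replicate 1, 247 without KO1 replicate 3, 198 without WT replicate 1 and 273 without WT replicate 2. It rose with the spread taken from all libraries of the condition and with a replicate block, as given in the part on processing. The KO2 count was 972, 912 and 883 without KO2 replicates 1, 2 and 3, 1029 and 1017 without WT replicates 1 and 2, and 2860 without WT replicate 3. The shared count was 106 and 119 without KO1 replicates 1 and 3 and 84 and 121 without WT replicates 1 and 2.

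With differentiation and LPS THBS1 reached 41913 ± 1273 in KO2 against 768 ± 199 in WT (55.8-fold, log2 change 5.80, SE 0.17, adjusted p = 1.32e-09) and 4585 ± 2502 in KO1 against 910 ± 238 (4.70-fold, log2 change 2.23, SE 0.28, adjusted p = 0.00011). KSR1, a scaffold of the RAF and MEK cascade (chromosome 17, 27456470 to 27626438), was 9.07-fold and 42.3-fold higher in KO1 and KO2. The EGF-receptor ligand AREG was 6.59-fold and 19.99-fold higher, and the granulocyte growth factor CSF3 4.42-fold and 7.70-fold. The interleukin 23 subunit IL23A was 2.97-fold and 14.9-fold higher, and PTGS2, the inducible cyclooxygenase that feeds prostaglandin synthesis, 2.38-fold and 6.86-fold. NFKBIZ, a nuclear cofactor that NF-kB needs at secondary response genes (chromosome 3, 101827991 to 101861022), was 2.25-fold and 2.39-fold higher (adjusted p = 6.57e-06 and 2.35e-05), and SAMD9L, an interferon-induced antiviral gene, 3.15-fold and 3.22-fold. SIGLEC14 was 153-fold and 8.70-fold lower, GRAMD1B 41.8-fold and 54.98-fold, and the nucleolar protein NCL 2.07-fold and 2.73-fold. KYNU was listed at 0 in KO1 against 91.2 ± 30.4 in WT and stood at 2.20 ± 3.81 in KO2 against 76.9 ± 25.5 (log2 change -5.26, SE 0.76, adjusted p = 0.000438).

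This condition gave 3712 changed genes of 13049 in KO1 (1927 higher, 1785 lower) and 3866 of 12915 in KO2 (1990 higher, 1876 lower), 1144 and 1605 of them at least 2-fold. Both clones moved the same way at 1820 genes (875 higher, 945 lower; 540 expected) and opposite ways at 93. Interferon-response genes were higher for 26 of 37 in KO1 and 31 of 37 in KO2, with 0 and 1 lower (27 and 0, 32 and 1 adjusted over the list alone; camera adjusted p = 1.75e-13 and 1.47e-14, and 0.361 and 0.439 with an estimated correlation). MYC targets and ribosome biogenesis genes were lower for 29 and 26 of 36, with 1 and 1 higher (31 and 1, 29 and 1 adjusted over the list alone; 0.349 and 0.439 with an estimated correlation). NF-kB targets were higher for 17 and 15 of 29, with 1 and 3 lower (18 and 2, 16 and 4 adjusted over the list alone; 0.112 and 0.439 with an estimated correlation). Among LPS-induced cytokines and chemokines, 14 of 25 and 11 of 24 were higher and 2 and 3 lower (16 and 2, 11 and 5 adjusted over the list alone; 0.349 and 0.444 with an estimated correlation). The KO1 count was 2456 and 2377 without WT replicates 1 and 2, the KO2 count 2331 and 2329, and the shared count 970 and 983.

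**Figure D2:**
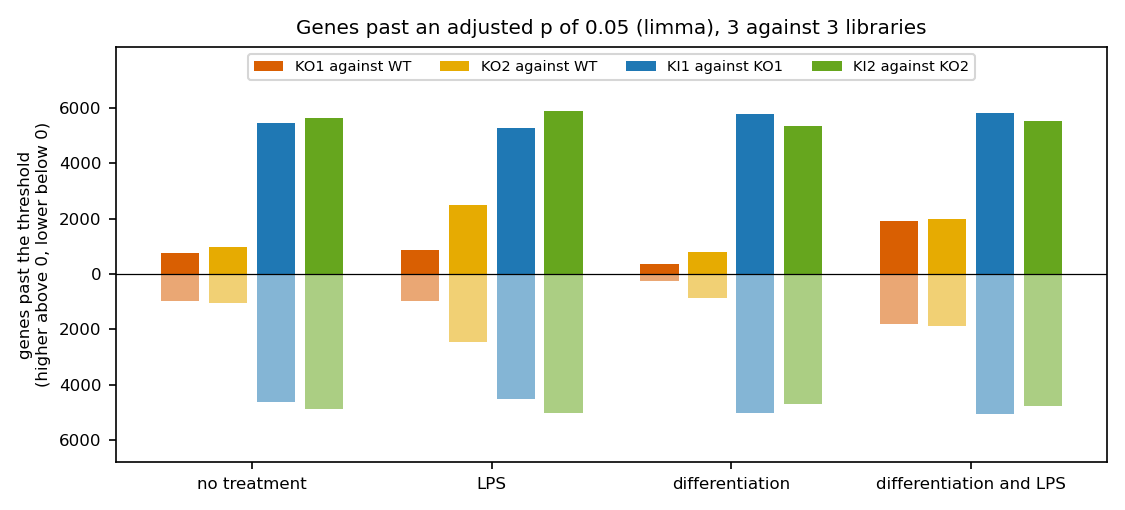
Number of genes past the limma threshold in each comparison and condition, with higher genes as bars above 0 and lower genes as bars below 0. The KI against KO bars exceed every KO against WT bar.

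Genes of the leukotriene and prostanoid pathway itself went both ways in the KO clones. Without treatment 6 were higher and 2 lower of 29 in KO1, and 4 and 2 of 30 in KO2 (7 and 3, 5 and 2 adjusted over the list alone). With LPS 4 and 4 of 28 changed in KO1 and 7 and 8 of 31 in KO2 (5 and 4, 8 and 8 adjusted over the list alone). After differentiation 1 and 0 of 28 changed in KO1 and 3 and 5 of 27 in KO2 (4 and 2, 3 and 6 adjusted over the list alone), and with LPS as well 5 and 5 of 29 and 6 and 6 of 31 (5 and 6, 7 and 9 adjusted over the list alone). Camera called this list in 0 of these 8 fits, the smallest adjusted p being 0.163. Untreated KO1 had a median of -0.12 and a mean of 0.03 over the list, so its sign was not settled.

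**Figure D3:**
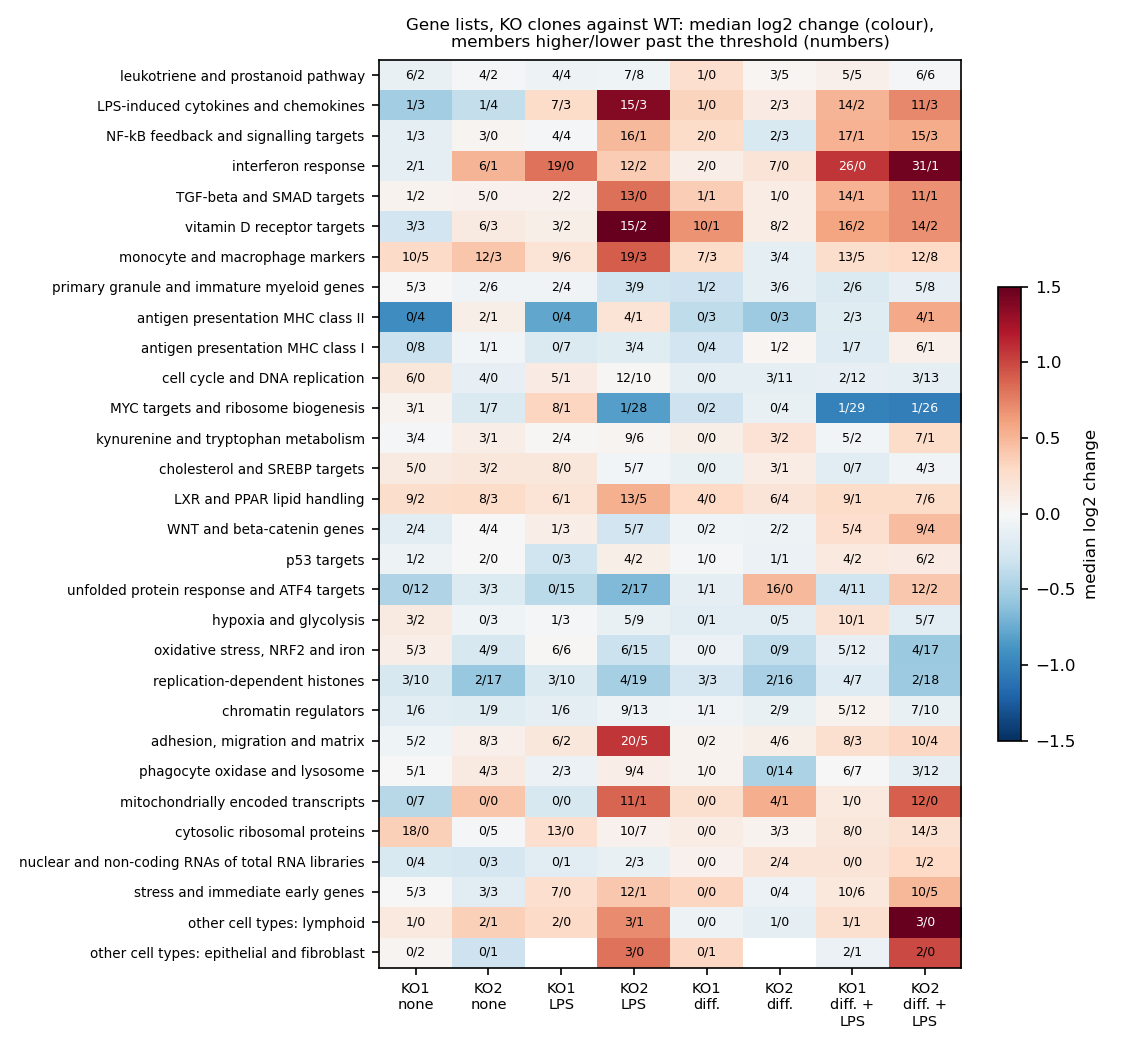
Median log2 change of each gene list in KO1 and KO2 against WT in the 4 conditions, as colour limited to 1.5 either way, with the number of members higher and lower past the threshold printed in each cell and blanks where fewer than 5 members were tested. With differentiation and LPS the interferon-response cells read 26 and 0 for KO1 and 31 and 1 for KO2.

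Both KO clones were compared with the same 3 WT libraries, which alone makes their changes alike. Across genes, which are not independent replicates, the changes of KO1 and KO2 correlated at r = 0.51 without treatment, 0.41 with LPS, 0.50 after differentiation and 0.63 with both. Simulated unchanged groups that shared controls gave 0.50 in each condition, which r exceeded clearly with both treatments alone. Their covariance was 0.0520, 0.0499, 0.0593 and 0.0574 in the 4 conditions, against 0.170, 0.182, 0.157 and 0.317 measured. In the simulation 0 genes were called alike in 20 simulated runs of each condition by limma, with at most 0.15 calls per run in a clone. The WT line has 3 libraries per condition and cannot be divided between the clones, so the share of this count that comes from the controls is unknown.

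KO1 and KO2 also differed from each other. The neuronal transcript host MIR124-1HG differed by a log2 value of -9.07 with LPS and -8.49 with differentiation and LPS, both in the direction of more in KO2. With LPS, THBS1 was lower in KO1 than in KO2 by a log2 value of -6.32 (SE 0.18, adjusted p = 1.54e-13), IL1B by -2.63 (SE 0.13, adjusted p = 1.12e-10) and CD14 by -1.92 (SE 0.23, adjusted p = 5.2e-06). IFIT1 was higher in KO1 by 2.78 (SE 0.46, adjusted p = 0.000118) and MYC by 0.65 (SE 0.10, adjusted p = 8.56e-05), the call for MYC being lost with the spread taken from all libraries of the condition. Of 36 MYC target and ribosome biogenesis genes 32 were higher in KO1 with LPS and 1 lower, and of 14 mitochondrially encoded transcripts 1 was higher and 12 lower. Mitochondrial mRNAs took 15.2 to 19.04% of reads in KO2 with LPS, 7.93 to 8.55% in KO1 and 9.17 to 11.3% in WT, and without treatment 12.3 to 19.3%, 7.93 to 8.45% and 9.97 to 13.2%. Genes that differed between the clones numbered 2132 of 13104 without treatment (1080 higher in KO1, 1052 lower), 5036 of 12822 with LPS (2559 and 2477), 1856 of 13454 after differentiation (971 and 885) and 2488 of 13212 with both (1264 and 1224). The untreated count was 1287 and 1272 without KO1 replicates 1 and 2, and the count after differentiation was 1085, 1085 and 951 without KO2 replicates 1, 2 and 3. Each genotype is 1 line or 1 clone, so effects of the edit and of cloning were not separated within a clone.

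The knockout effect tested here is averaged over both clones, and its SE leaves out the spread between the clones. This effect changed with LPS for IL1B, whose log2 difference from the untreated effect was 2.86 (SE 0.20, adjusted p = 9.86e-09), and for the transcription factor RUNX3 (2.47, SE 0.17). The clones were unlike in this: the log2 change of IL1B went from -0.96 to 0.28 in KO1 and from -1.58 to 2.91 in KO2, and that of RUNX3 with LPS was 0.96 and 3.998. TNF, lower in both clones before LPS, had a difference of 1.65 (adjusted p = 0.00733). In differentiated cells LPS raised the knockout effect on the phosphatase DUSP1 by 2.24 (adjusted p = 0.00389), NFKBIZ by 0.82 (adjusted p = 0.00616) and the AP-1 subunit FOSL2 by 1.52 (SE 0.15, adjusted p = 1.17e-05). LPS altered the knockout effect for 119 of 13071 genes (103 higher, 16 lower) and LPS after differentiation for 312 of 13509 (203 higher, 109 lower). Interferon-response genes gave 7 higher and 0 lower of 36 in the last test, with a median of 1.04. The first count was 71 with the spread taken from all libraries of the condition, and the last 202 with no filter on low values. Both rose with a replicate block across conditions, as given in the part on processing. Without WT LPS replicate 3 the first count was 78, and without KO2 untreated replicate 2 it was 185. Without WT replicates 1 and 2 with differentiation and LPS the last count was 130 and 147, and without WT differentiated replicates 2 and 3 it was 195 and 205. Without KO1 replicate 3 with both it was 200, and without KO2 replicate 2 with both it was 500.

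The KI libraries held RNA classes that the WT and KO libraries nearly lacked, which bears on every KI against KO value below. The U3 snoRNA gene SNORD3A, which guides ribosomal RNA cleavage, stood at 66355 ± 29976 in untreated KI1 against 6.31 ± 5.50 in KO1, and MT-ND6, the subunit of complex I encoded on the other mitochondrial strand, at 289 ± 151 against 0.599 ± 1.04. Genes of snoRNAs took 0.524 to 2.22% of reads in the 24 KI libraries and 0.00724 to 0.0283% in the 36 others, and mitochondrial mRNAs 2.69 to 6.93% against 7.06 to 19.3%. The KI libraries had 11.2 to 20.5 M expected reads and 21840 to 23510 genes above 0, against 3.78 to 15.4 M and 16023 to 18058 in the others. Principal component 1 held 59.4% of the variance of 14209 genes, with every KI library between 92.6 and 116 and every other between -83.7 and -47.3. No KI library was made like a KO library by these measures, so genotype and library type cannot be told apart in a KI against KO value. For the 7SK RNA, reads lay on different overlapping gene models, and both models together gave 25879 reads per M in KI and 22581 in the others.

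**Figure D4:**
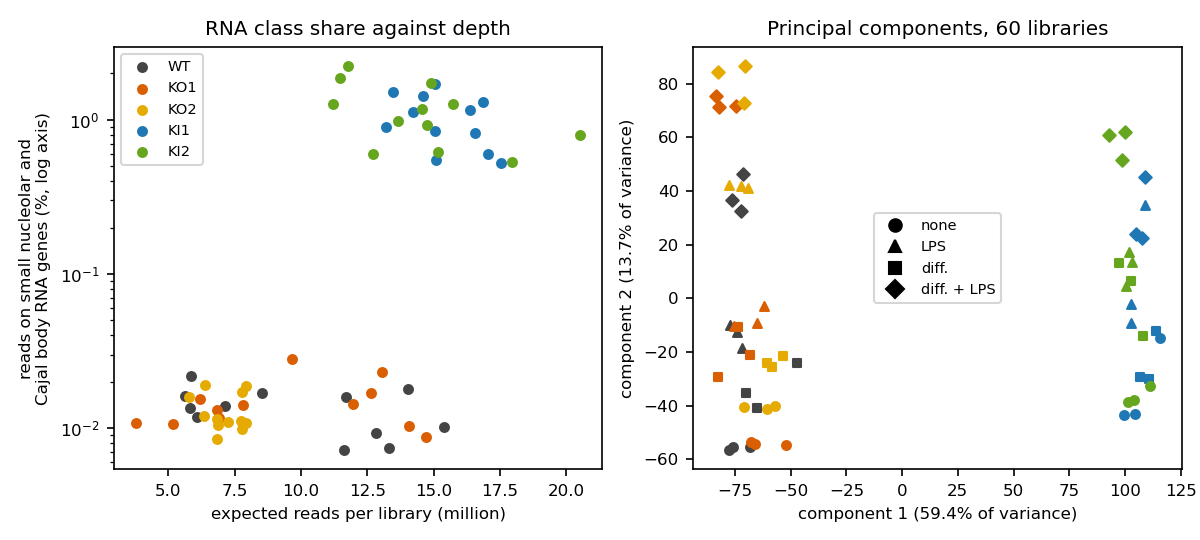
Left, the percent of reads on snoRNA and scaRNA genes on a log axis against M expected reads; right, principal components 1 and 2 with 59.4% and 13.7% of the variance, for 60 libraries coloured by genotype with marker shapes for condition. All KI libraries lie apart from the WT and KO libraries in both panels.

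Without treatment, TANC1 was lower in KI1 than in KO1 by 2.54-fold (SE of the log2 change 0.23, adjusted p = 0.000665) and lower in KI2 than in KO2 by 2.21-fold (SE 0.25, adjusted p = 0.00213), against its rise in both KO clones. GRAMD1B, far lower in KO than in WT, had a log2 change of 0.71 in KI2 against KO2 (adjusted p = 0.274). Interferon-induced IFIT1 was 83.2-fold higher in KI1 than in KO1 and 24.8-fold higher in KI2 than in KO2, and the ISG15 ligase HERC5 33.9-fold and 10.8-fold. KI1 replicate 3 carried much of the IFIT1 mean, 891 ± 1284, with 199 reads per M against 8.71 and 17.03 in replicates 1 and 2. The inhibitory RNase ZC3H12A was 3.43-fold and 4.29-fold lower and the chaperone PDIA6 4.04-fold and 7.13-fold higher. Changed genes numbered 10075 of 14190 for KI1 (5465 higher, 4610 lower) and 10523 of 14135 for KI2 (5650 higher, 4873 lower), and 8360 changed alike in both (4587 higher, 3773 lower; 3692 expected). Interferon-response genes were higher for 32 of 39 in KI1 and 27 of 35 in KI2, with 1 and 2 lower (32 and 1, 27 and 2 adjusted over the list alone; camera adjusted p = 0.000692 and 0.00171, and 0.84 and 0.496 with an estimated correlation). The median over all genes was 0.12 and 0.11 and moved to -0.00 and -0.01 with upper-quartile rescaling.

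With LPS KYNU was detected in KI1 at 209 ± 151, against a listing at 0 in KO1, and was 6.45-fold higher in KI2 than in KO2 (25.2 ± 5.99 against 4.87 ± 4.84, log2 change 2.69, adjusted p = 0.00985). EBI3, the shared subunit of interleukins 27 and 35, was 37.8-fold lower in KI1 than in KO1 (log2 change -5.24, SE 0.39, adjusted p = 1.3e-05) and 24.7-fold lower in KI2 than in KO2 (-4.63, SE 0.18, adjusted p = 2.6e-08). The neutrophil chemokine CXCL1 was 7.33-fold and 8.83-fold lower, and ZC3H12A 4.79-fold and 9.24-fold. The counts were 9802 of 13814 for KI1 (5274 higher, 4528 lower), 10887 of 14004 for KI2 (5884 higher, 5003 lower) and 8173 alike in both. NF-kB targets were lower for 19 and 23 of 29 and higher for 3 and 3 (19 and 3, 23 and 4 adjusted over the list alone; camera adjusted p = 0.00536 and 5.08e-05, and 0.805 and 0.664 with an estimated correlation).

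After differentiation TBC1D9, a regulator of Rab GTPases, was 8.86-fold higher in KI1 than in KO1 and 20.4-fold higher in KI2 than in KO2, and NAV3, a microtubule protein, 63.8-fold and 105-fold. CCL2 was 9.74-fold and 32.0-fold lower, and IL1RN, the natural inhibitor of interleukin 1, was 6.97-fold and 4.54-fold lower. The neutrophil chemokine CXCL8 was 14.6-fold and 8.65-fold higher, and the interferon-induced IFI44 84.7-fold and 73.8-fold. The counts were 10809 of 14425 for KI1 (5787 higher, 5022 lower), 10051 of 14121 for KI2 (5355 higher, 4696 lower) and 8357 alike in both. Interferon-response genes were higher for 21 of 35 and 26 of 34, with 4 and 2 lower (21 and 4, 26 and 2 adjusted over the list alone), and camera called this list for KI2 (adjusted p = 0.00107, and 0.913 with an estimated correlation) and not for KI1 (0.0592).

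With differentiation and LPS CSF3 was 146-fold lower in KI1 than in KO1 (12.3 ± 2.22 against 1965 ± 422, log2 change -7.19, SE 0.23, adjusted p = 1.4e-07) and 224-fold lower in KI2 than in KO2 (11.3 ± 3.06 against 2757 ± 675, -7.80, SE 0.25, adjusted p = 1.5e-07). THBS1 was 10.7-fold lower in KI1 and 152-fold lower in KI2, KSR1 16.3-fold and 42.7-fold, and CCL2 28.0-fold and 99.4-fold. The urokinase receptor PLAUR was 6.78-fold and 12.1-fold lower and the cell-cycle inhibitor CDKN1A 7.07-fold and 18.1-fold. KYNU went the other way, at 164 ± 42.0 in KI1 against a listing at 0 in KO1, and 9.59-fold higher in KI2 than in KO2 (adjusted p = 0.00771). The counts were 10879 of 14357 for KI1 (5833 higher, 5046 lower), 10263 of 14181 for KI2 (5518 higher, 4745 lower) and 8512 alike in both. NF-kB targets were lower for 23 and 24 of 29 and higher for 3 and 2 (23 and 3, 24 and 2 adjusted over the list alone; camera adjusted p = 3.69e-06 and 9.83e-07, and 0.304 and 0.714 with an estimated correlation). LPS-induced cytokines and chemokines were lower for 20 of 25 and 19 of 24 and higher for 3 and 3 (20 and 3, 19 and 3 adjusted over the list alone; 0.304 and 0.714 with an estimated correlation).

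**Figure D5:**
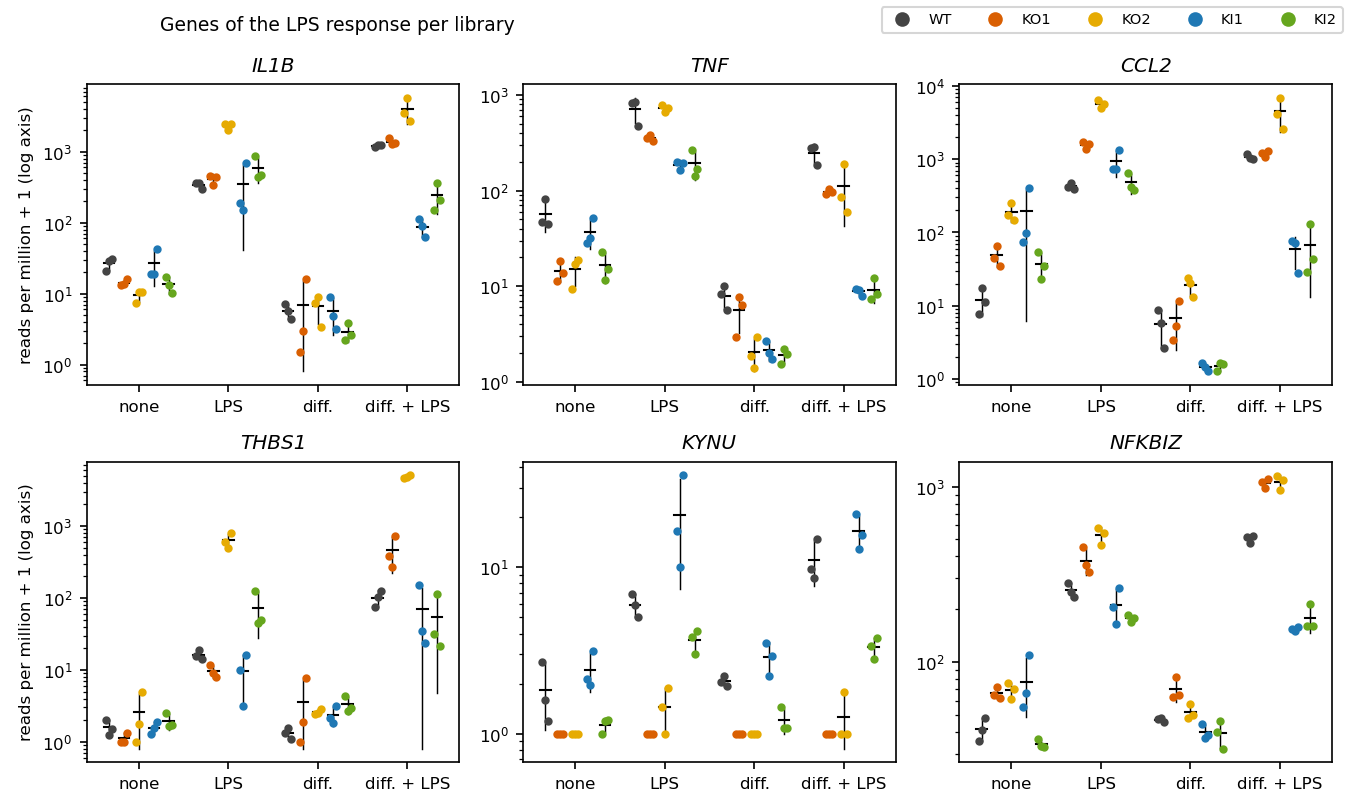
IL1B, TNF, CCL2, THBS1, KYNU and NFKBIZ in reads per M plus 1 on log axes, 1 point per library, for each genotype and condition, with a bar at the mean and a line for the SD. THBS1 with differentiation and LPS averages 4849 reads per M in KO2 and 54.0 in KI2, whose libraries differ in type as well as genotype.

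Some genes changed in both KO clones and in the opposite direction in both KI clones, called changed back below. They included TANC1 without treatment and with LPS, and KYNU with LPS and with both treatments. TBC1D9 and NAV3 were among them after differentiation, and KSR1 with both. The term gives the direction alone, since KI was not compared with WT. Untreated TANC1 fell in KI by far less than it had risen in KO, while KSR1 with both treatments fell in KI1 by more than it had risen in KO1. After differentiation TBC1D9 was 17.5-fold and 29.5-fold lower in KO1 and KO2 than in WT, and NAV3 10.1-fold and 9.42-fold lower. There were 86 such genes without treatment, 226 with LPS, 99 after differentiation and 737 with both. Genes that moved the same way in the KO and KI comparisons numbered 235, 252, 22 and 358, and the numbers expected for the reversed direction if calls were independent were 165, 250, 66.4 and 554. A KO library enters both comparisons with opposite sign, so noise in it favours reversal. Between clones that shared no library, KO1 against WT and KI2 against KO2 correlated across genes at 0.20, 0.08, -0.28 and -0.20 in the 4 conditions, and KO2 against WT and KI1 against KO1 at 0.14, 0.07, -0.05 and -0.19. The untreated count was 55 without KO1 replicate 1 and 44 and 45 without WT replicates 1 and 2, and the LPS count 142 and 119 without WT replicates 1 and 2. After differentiation it was 42 and 48 without KO1 replicates 1 and 3, 32 and 53 without WT replicates 1 and 2, and 58, 61 and 61 without KO2 replicates 1, 2 and 3. With both treatments it was 412 and 433 without WT replicates 1 and 2.

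A constant library difference drops out when the KI against KO change is compared between conditions. After differentiation the LPS response of NFKBIZ was lower in KI than in KO by a log2 difference of -2.28 (SE 0.15, adjusted p = 2.01e-09), and that of IL1B by -3.90 (SE 0.74, adjusted p = 0.00106). The difference was also negative for TNF (-2.88, SE 0.49, adjusted p = 0.00034), CSF3 (-6.63, SE 0.68, adjusted p = 8.75e-07) and THBS1 (-5.80, SE 0.96, adjusted p = 0.000243). In cells not differentiated, EBI3 had a difference of -4.09 (SE 0.47, adjusted p = 7.77e-05), TNF of -2.31 (adjusted p = 0.000144) and IL1B of -2.08 (adjusted p = 0.0111). LPS after differentiation altered the KI effect for 1775 of 14510 genes (712 higher, 1063 lower; 40.1% higher, but 57.0% with upper-quartile rescaling and 59.6% with protein-coding genes alone), LPS alone for 163 of 14200 (32 higher, 131 lower) and differentiation for 116 of 14379 (52 higher, 64 lower). With a replicate block across conditions, which the KI libraries follow, the counts were 2990, 660 and 232. Of LPS-induced cytokines and chemokines 0 were higher and 16 lower of 23 after differentiation (median -2.41), and of NF-kB targets 0 and 21 of 29 (median -1.61). In cells not differentiated the medians of these lists with LPS were -1.76 and -0.84. The count for LPS alone was 256 without KI1 LPS replicate 3 and 99 without KI2 LPS replicate 2. The count for differentiation was 72 without KO2 differentiated replicate 1, 71 without KI1 differentiated replicate 2, 71 without KI2 differentiated replicate 1, 76 without KO1 untreated replicate 1, 179 without KI1 untreated replicate 3 and 67 without KI2 untreated replicate 1.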

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

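All tests of explanations in this part were chosen after the result was seen, except the strand test and the counts of other splits, which were chosen before.

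What drew attention in the KO clones was that 2 clones of 1 genotype differed from each other by a test of the difference itself. Without treatment KO1 lay below KO2 in PTGIS, which makes prostacyclin, by a log2 difference of -4.05 (SE 0.16, adjusted p = 4.39e-10), in BEX3, a regulator of cell death, by -8.10, and in PDE6G, a phosphodiesterase subunit of photoreceptors, by -7.87. With LPS it lay below KO2 in THBS1 by -6.32, in CHI3L1, a chitinase-like macrophage protein, by -3.11, and in the non-coding host gene MIR124-1HG by -9.07. After differentiation the values were -7.63 for the T-cell transcription factor NFATC2, -7.62 for BEX3 and -5.12 for the non-coding DANT2, and with LPS as well -8.49 for MIR124-1HG, -7.72 for PDE6G and -2.09 for the plasminogen activator PLAU. The clones differed at 2132 genes without treatment, 5036 with LPS, 1856 after differentiation and 2488 with both. Without KO1 replicates 1 and 2 the untreated count was 1287 and 1272, and without KO2 replicates 1, 2 and 3 the count after differentiation was 1085, 1085 and 951. A count as large arose in 1 of 100 drawn splits of the 9 libraries, the real one, without treatment, with LPS and after differentiation. The highest other count was 1146, 3936 and 474 in these. With both it arose in 2 of 100 (highest other 2908). Most draws mixed WT, KO1 and KO2 libraries in 1 group, which widens its spread, and the median of the other draws was 0. These draws therefore do not decide on chance.

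The first pattern weighed is that KO2 departed from WT far more than KO1 with LPS, with 4977 changed genes against 1829, among them IL1B and THBS1. Higher precision of the KO2 libraries was excluded, since the median standard error of KO2 against WT was 1.03 times that of KO1 (a ratio of 1.035). Differentiated cultures labelled as LPS alone were excluded as well: CYP24A1, which was at 23.7 reads per M or more in every differentiated library, was at most 0.158 in KO2 with LPS. Differences between the 2 single clones, 5036 genes, and an effect of the knockout that 1 clone shows more than the other cannot be told apart, because each clone is 1 line. KO2 libraries also held more mitochondrial mRNA with LPS, 15.2 to 19.04% of reads against 7.93 to 8.55% in KO1, but without treatment the shares were also apart (12.3 to 19.3% and 7.93 to 8.45%) while the counts were close (2044 and 1729). The share is thus not particular to LPS, and a difference in RNA quality or cell state behind it was not tested.

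The knockout effect, averaged over both clones, differed between conditions, again by a test of the difference. Its SE reflects the spread between libraries and leaves out that between the clones, which were unlike for IL1B and RUNX3. LPS raised the averaged effect for RUNX3 by 2.47 (SE 0.17, adjusted p = 9.86e-09), IL1B by 2.86 and the TNF receptor TNFRSF1B by 1.41, and 119 genes differed in all. Differentiation raised it for the hearing-loss gene PDZD7 by 2.21 and the membrane protein gene PRRT4 by 1.63, altered it for haptoglobin (HP) by -1.65, and 43 of 13333 genes differed (25 higher, 18 lower), but 15 with no filter on low values and 25 with the spread taken from all libraries of the condition. LPS after differentiation raised it for the nuclear receptor coactivator PNRC1 by 1.52, the ubiquitin ligase RNF24 by 1.54 and FOSL2 by 1.52, and 312 genes differed. A count as large arose in 3 of 100 draws for the first (highest other 1512). It arose in 1 of 100 for the second (highest other 14) and 1 of 100 for the third (274). The median of the other draws was 0 for each. Most draws mixed lines within a group, which widens its spread, so these draws do not decide on chance. Draws with several times the real count in the first point to a structure of the samples: in both of them all 3 KO2 libraries with LPS stood as WT. The first count was 78 without WT LPS replicate 3 and 185 without KO2 untreated replicate 2. The second was 26 and 22 without KO1 differentiated replicates 1 and 3, 14 and 11 without WT differentiated replicates 1 and 3, 18, 22 and 20 without KO2 differentiated replicates 1, 2 and 3, 14 and 19 without KO1 untreated replicates 2 and 3, 8, 14 and 88 without WT untreated replicates 1, 2 and 3, and 18 without KO2 untreated replicate 3. The third was 130 and 147 without WT replicates 1 and 2 with differentiation and LPS, 200 without KO1 replicate 3 and 500 without KO2 replicate 2 of that condition, and 195 and 205 without WT differentiated replicates 2 and 3.

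The KI effect, averaged over both KI clones in the same way, differed between conditions too. LPS altered it for CHI3L1 by -2.21 (SE 0.21, adjusted p = 5.75e-06) and EBI3 by -4.09, with 163 genes in all. Differentiation altered it for the neuronal membrane proteins SLITRK5 by 1.99 and AMIGO3 by -3.54 and for the endocytosis adaptor HIP1 by -1.18, with 116 genes in all. LPS after differentiation altered it for PLAUR by -2.18 (SE 0.14, adjusted p = 2.01e-09), the cyclic AMP phosphodiesterase PDE4D by -3.57 and NFKBIZ by -2.28, with 1775 genes in all. As large a count arose in 4 of 100 draws for LPS (highest other 6532), 2 of 100 for LPS after differentiation (5741) and 5 of 100 for differentiation (9305). Nearly every draw put both library types in 1 group, which widens its spread, so these draws do not decide on chance. Draws that called several times the real count point to a structure of the samples: the number of KI libraries placed as KI differed by 3 or 4 between their 2 conditions. The count for LPS was 256 without KI1 LPS replicate 3 and 99 without KI2 LPS replicate 2. The count for differentiation was 72 without KO2 differentiated replicate 1, 71 without KI1 differentiated replicate 2, 71 without KI2 differentiated replicate 1, 76 without KO1 untreated replicate 1, 179 without KI1 untreated replicate 3 and 67 without KI2 untreated replicate 1.

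The second pattern weighed is that LPS and NF-kB genes responded less to LPS in differentiated KI than in differentiated KO cells. The median differences were -2.41 for the cytokine list and -1.61 for the NF-kB list. In cells not differentiated they were -1.76 and -0.84, so the pattern was not particular to differentiated cells. Differentiation without LPS gave -1.16 and -0.07, so the cytokine list was also lower without LPS. An additive library difference of the KI libraries would leave a median near 0, and the 52 members of both lists had -1.89. A proportional compression of all changes in KI libraries would damp each response in both directions. LPS responses were damped both ways: the 752 genes that LPS raised at least 2-fold in WT had a median KI difference of -1.03 and the 802 that it lowered had 0.755. Differentiation responses were not: the 504 genes that it raised had -0.054 (quartiles -0.45 and 0.32) and the 348 that it lowered had -0.31, away from damping. Compression of all changes was therefore excluded, and damping limited to LPS responses was not. A weaker LPS stimulus in the cultures of the KI series remains open. Interferon-response genes had a median of -0.46 in cells not differentiated (1 of 39 past the threshold, lower) and -0.95 in differentiated ones (11 of 37). Differentiation alone, with no LPS, gave -0.94, so these medians are not particular to LPS. A biological effect of the knock-in remains open beside it and was not separated from it.

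The third pattern weighed is that all KI libraries differ from all WT and KO libraries in detected genes and in RNA classes. Sequencing depth was excluded: at 3.5 M reads the lowest KI library was expected to show 17855 genes and the highest other 16268. Counting without regard to strand in KI alone was not seen among the 162 genes with a value in KI and 0 in every KO library. Of these, 27.8% overlap a gene on the other strand, against 54.2% of 15189 genes, a ratio of 0.512. Genes with some reads in KO were left out of that set, so the explanation was not excluded for them. A library preparation of the KI libraries that recovers other RNA classes remains open. Without 7SK, the nearest KI and other libraries were at least 5.73-fold apart in each of 3 classes, 18.5-fold in snoRNAs and 246-fold in snRNAs. These gaps restate the pattern, so they do not decide on its cause. A change of these RNA classes by genotype was not tested, since no KI library was of the other type.

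Other splits were counted for the remaining counts. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and the real split alone (1 of 10) reached its count in each table. The highest other was 1 for untreated KO2 against WT (real 2044), 2 for differentiated KO2 against WT (real 1650), and 0 in the other 14 tables, with real counts from 597 to 10887. The gene list tests also had 10 splits, with 142 calls in the real one, 120 in the highest other and a median of 106. Each other split set 2 libraries of a genotype against 1, so part of the real contrast stayed in it. These list counts therefore do not decide on chance. For genes changed alike in both KO clones, a count as large arose in 1 of 100 draws without treatment (real 575, highest other 136). It arose in 2 of 100 after differentiation (237, 343) and 1 of 100 with both treatments (1820, 1165). With LPS it arose in 7 of 100 (854, 2872), so chance was not excluded there. Draws with several times the real count point to a structure of the samples: in the 6 with more than the real count all 3 KO2 libraries stood as WT. Most draws mixed WT, KO1 and KO2 libraries in 1 group, which widens its spread, and the median of the others was 0. They do not decide on chance in the other conditions either. Genes changed alike in both KI clones numbered 8360, 8173, 8357 and 8512. Genes changed in both KO clones and in the opposite direction in both KI clones numbered 86, 226, 99 and 737. Both counts had 0 in the highest of the other draws and 1 of 100 in each condition. These draws mix the 2 library types within groups, which alone leaves few calls, so they do not decide on chance. Reversed genes were also fewer than the 165 and 250 that independent calls would give without treatment and with LPS.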

How the results depend on the processing

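Of the alternatives, voom weights, the fit of protein-coding genes alone and the replicate block across conditions were chosen after the data were seen. The planned count models were not run because whole counts were not recovered. A pseudocount of 5, upper-quartile rescaling, voom weights and protein-coding genes alone kept every count of genes within 1.5 times its reported value. The list tests, run with the first 2 of these alone, stayed within it too. They moved the balance in a few: in the KI effect of LPS after differentiation 40.1% of called genes were higher, 57.0% with upper-quartile rescaling and 59.6% with protein-coding genes alone. In genes changed back in KI with both treatments 64.99% were higher in KO and 53.9% with protein-coding genes alone, and in the KO effect of differentiation 58.1% and 47.9%. With no filter on low values more genes were adjusted for: genes changed back in KI after differentiation numbered 65 (99 reported), the KO effect changed for 15 with differentiation (43) and for 202 with LPS after it (312), and the gene list tests gave 216 calls (142). With the spread taken from all libraries of the condition, differentiated KO1 had 956 changed genes (597), and the KO effect changed for 71 with LPS (119) and 25 with differentiation (43). A replicate block gave 3099 in untreated KO1 (1729), 978 in differentiated KO1 (597), 388 alike in both differentiated KO clones (237), 160 changed back in KI after differentiation (99), and a changed KO effect for 194 with LPS (119) and 100 with differentiation (43). All 3 correlations of libraries of 1 number passed 0.1 in 0 of 16 tables, and they ran from -0.09 to 0.23. Those of replicate 3 ran from 0.05 to 0.19 in the KO against WT tables. The labels do not say whether numbers pair, so a deviation shared by number was not excluded. A replicate block across conditions, pairing libraries of 1 number within a line or clone, gave a changed KO effect for 397 with LPS (119), 116 with differentiation (43) and 623 with LPS after it (312), and a changed KI effect for 660 (163), 232 (116) and 2990 (1775), and changed none of the 28 calls of named genes in these tests. Across conditions, all 3 correlations passed 0.1 in 5 of 6 pairs of groups in the KI clones and 1 of 9 in WT and KO. An estimated correlation left 0 list calls (142). The cause was not tested for the spread, the block or the correlation.

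Leaving out 1 library in turn gave these ranges, with fewer samples as part of the cause. Without treatment KO1 had 925 to 2351 changed genes, KO2 930 to 2104, both KO alike 241 to 729, changed back in KI 44 to 112, and different between clones 1272 to 2209. With LPS KO1 had 913 to 1996, both alike 453 to 883, and changed back 119 to 247. After differentiation KO1 had 198 to 460, KO2 883 to 2860, both alike 84 to 250, changed back 32 to 101, and different between clones 951 to 2276. With both treatments KO1 had 2377 to 3629, KO2 2329 to 4348, both alike 970 to 2069, and changed back 412 to 873. The KO effect changed for 78 to 185 genes with LPS, 8 to 88 with differentiation and 130 to 500 with LPS after it, and the KI effect for 99 to 256 with LPS and 67 to 179 with differentiation. Counts that stayed within 1.5 times were all KI against KO counts, both KI alike, KO2 with LPS (3901 to 4595), the clone difference with LPS (4224 to 5181) and with both treatments (1698 to 2354), and the KI effect of LPS after differentiation (1415 to 1905).

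Among named genes 316 calls were lost and 9 gained on leaving out 1 library, 56 lost with the common spread, 26 without a filter, 4 with the block, 3 with voom, 2 with upper-quartile rescaling and 1 with protein-coding genes alone. Calls gained were 5 with the block, 2 with the common spread, 1 with voom and 1 with protein-coding genes alone. Values that changed sign were not called as reported. With protein-coding genes alone SESN1 in differentiated KO1 was -0.00016 (0.03 reported). On leaving out 1 library the values in differentiated KO1 ran from -0.071 (WT replicate 3) to 0.11 for SESN1, which was also -0.02 without KO1 replicate 1, from -0.25 to 0.074 (KO1 replicate 2) for SRC (-0.10), from -0.31 to 0.20 (KO1 replicate 2) for STARD4 (-0.12), and from -0.44 to 0.038 (KO1 replicate 2) for NEAT1 (-0.26). They ran from -0.047 (KO1 replicate 3) to 0.54 for MT-ND4L (0.28) and from -0.013 (WT replicate 3) to 0.35 for HSPB1 (0.14). With both treatments in KO1 they ran from -0.051 (KO1 replicate 3) to 0.42 for MT-ND4L (0.17), from -0.094 (WT replicate 1) to 0.33 for ALOX5 (0.08), which was also -0.0032 without KO1 replicate 3, and from -0.26 to 0.043 (KO1 replicate 1) for the RN7SL1 gene model (-0.12). NCL in untreated KO1 ran from -0.020 (KO1 replicate 3) to 0.13 (0.05). ALOX5 ran from -0.26 (KI1 replicate 3) to 0.60 in untreated KI1 (0.18) and from -0.18 (KI2 replicate 1) to 0.67 in differentiated KI2 (0.24). In KO2 IFIT1 with LPS ran from -0.70 to 0.15 (KO2 replicate 2; -0.29), and after differentiation CD14 from -0.37 to 0.16 (KO2 replicate 2; -0.14), also 0.085 without WT replicate 3, and CYP24A1 from -0.81 to 0.50 (WT replicate 3; -0.26), also 0.12 without KO2 replicate 2. Depth limits genes near a mean of 10. In simulation fewer 1.5-fold changes were recovered in KI1 against KO1 (9.38%) than in KO1 against WT (42.4%). That simulation made 87 calls for KI1 against KO1, while the measured untreated fit made 10075. The adjusted threshold was thus stricter in the simulation, and its share does not give the power of the measured KI tests.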

Other observations

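The test of the hypothesis in this part was chosen after the result was seen.

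KO clones with LPS shared further changes that the comparisons did not dwell on. The serine synthesis enzyme PSAT1 was 3.04-fold lower in KO1 and 3.91-fold lower in KO2 than in WT. The cholesterol exporter ABCA1 was 2.55-fold and 5.99-fold higher. The matrix proteoglycan VCAN was 2.25-fold and 11.7-fold higher.

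Further genes differed from WT with differentiation and LPS. HBEGF, a ligand of the EGF receptor, was 2.08-fold and 7.84-fold higher in KO1 and KO2, PTGES, which makes prostaglandin E2, 2.69-fold and 10.9-fold, and the crosslinking enzyme TGM2 2.76-fold and 19.5-fold. CIITA, the master regulator of MHC class II genes, was 2.72-fold and 4.04-fold higher while its target HLA-DRA was 15.03-fold and 2.18-fold lower, the KO2 value losing its call with the spread taken from all libraries of the condition. The lysosomal protein CD68 was 2.22-fold and 1.85-fold lower and the integrin ITGA4 2.63-fold and 5.31-fold lower.

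A hypothesis from these values is that the knockout may raise, and the knock-in lower, the same LPS responses. Pairs of clones that share no library were compared across genes for the change of their effect with LPS. KO1 against WT and KI2 against KO2 correlated at -0.258 over 13017 genes, and KO2 against WT and KI1 against KO1 at -0.286 over 12977 genes, while in cells not differentiated the values were -0.060 and -0.018. By sign alone, with no threshold, 34 of 50 and 38 of 51 members of the LPS and NF-kB lists were higher in KO and lower in KI after differentiation. In cells not differentiated 31 of 48 and 38 of 51 were. Members lower in both KO and KI numbered 14 and 11 after differentiation, and 14 and 6 otherwise. Most members were thus lower in KI whatever their sign in KO. Few passed the threshold for the KO effect, 3 higher and 1 lower of 23 and 5 and 0 of 29 after differentiation, and 4 and 0 of 23 and 3 and 0 of 29 otherwise. Whether the pattern needs differentiation is left open. Genes are not independent replicates, and a weaker LPS stimulus in the whole KI series would give the same sign if the knockout raises the response, so the hypothesis is not separated from that.

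KI1 replicate 3 stood apart from its group in all 4 conditions, on principal component 2 at -14.8 without treatment, 34.8 with LPS, -12.4 after differentiation and 45.2 with both, where the higher of the other 2 was at -43.1, -2.25, -29.4 and 23.8. Leaving it out gave 10177 changed genes in untreated KI1 against KO1 and 10151 with LPS.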
